A study of Homo sapiens with 4 samples.

How the data were processed

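Total RNA of erythroid cells grown from human CD34-positive cells was extracted with a silica-column kit, per the labels' protocols, and sequenced in 4 libraries, 2 from day 7 and 2 from day 10 of culture. Each library has 1 deposited table that lists 48104 RefSeq transcripts of 25680 gene symbols, with a whole-number read count, an FPKM value and a TPM value per transcript, per the file headers. The aligner, the counting program and its strand setting, and the handling of reads with several placements are not given in the sources used here. The deposited FPKM equals the count divided by a transcript length and by the table's count total: the lengths this implies were whole to within 0.001 bases for each transcript above 0 in each library. The deposited TPM was not used. The tests used the deposited counts, and FPKM served only to check the tables and to obtain lengths.

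Reads appear to be counted for each transcript they overlap: in 92.7% of 5356 genes with several transcripts and a mean of at least 100 counts, the second transcript had at least 80% of the count of the first. Summing transcripts would count such reads several times, so the transcript with the highest mean count over the 4 libraries stood for its gene. This rule had been fixed in advance for files of this kind, as had the groups, tests, gene lists and the rule for named genes, before the data were examined. Genes on the Y chromosome and XIST were left out (106 symbols), leaving 25574 genes. Gene names are those of the files, and 97.7% of transcripts matched a current RefSeq table (GRCh38.p14), which was used for names and neighbours only. The files name an older build, so no coordinates are given.

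Libraries were scaled by TMM, genes kept by filterByExpr, and day 10 compared with day 7 by edgeR's quasi-likelihood test (edgeR 4.0.16, robust, in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library size. The SE of a log2 fold change is its size divided by the root of the F statistic. The common dispersion was 0.00125, a coefficient of variation of 3.54% between replicates. Replicates differed by more than counting noise, with a median chi-square per gene of 0.753 on day 7 and 1.09 on day 10 against 0.455 for counting noise alone, and were treated as separate libraries. No spike-in scaling was used here, so every change is relative to the other transcripts.

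Gene lists (49, with 1477 entries in all, some shared between lists) covered the erythroid programme, transcription and chromatin, growth and cell cycle, metabolism, stress, RNA handling and markers of other blood cells. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2. None of the mitochondrially encoded mRNAs was analysed here, and the lymphocyte list had too few tested members. Globin shares were compared by an exact two-sided permutation test. Named genes are the 8 largest rises and 8 largest falls among called genes with at least 20 CPM in the higher group and both day 10 values above, or both below, both day 7 values. Within each list they are up to 4 called members with the largest change in the main direction and up to 2 in the other, at 5 CPM or more, and genes fixed by name were taken whatever their result; some genes the rule takes are not reported here. The rule takes 274 genes, of which 120 are named; that choice, made mostly for length, was made after their values were seen, with their direction under library totals among the things looked at. With library totals, 28 of the 274 turned round, against 15 of the 120 named. NELFE and RPS18 were also named after their values were seen.

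Alternatives were DESeq2 size factors, library totals, TMM without globin genes, other count filters, DESeq2 1.42.0 with its Wald test, the replicate number as a block, leaving out each library, a test against a fold of 2, summed counts, transcripts in place of genes, an estimated correlation and fry. With 1 library left out, the lone library of a day was assumed to vary like the other day. Upper-quartile factors, leaving out the histocompatibility block, an estimated fold of 2 and, for lists, subtracting the median log2 fold change of each of 10 length classes were added after seeing the data. The steps were tested on simulated data for 13627 genes, of which 200 were changed. The count filter kept 13180 genes, and a changed gene that it dropped counted as missed. Of changes of 1.23-fold 50% were called, with 72% at 1.5-fold, 74% at 2-fold and 90% at 4-fold, and 9 calls fell among unchanged genes. Of 40 random lists in simulated data, 0 were called by camera, and a list of 40 raised genes was. Simulated genes were drawn independently and most were unchanged. These checks therefore do not cover lists with correlated members, or the scaling when most genes change.

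Some genes cannot be read on their own. Reads with 2 equal placements appear to be counted at both, since NUDT4 and its pseudogene NUDT4P1 have mean counts of 55759 and 55332. Most protein-coding genes of the major histocompatibility block, between TRIM27 and DAXX, have counts near 0, with 9 of 158 reaching a mean of 100. The list members in the block are TRIM10, NELFE, GTF2H4, EHMT2, DAXX, RPS18, HSPA1A, HSPA1B, IER3, AIF1 and HLA-DRA. Exons of 16 of the 120 named genes overlap another measured gene in GENCODE v29, among them MIF, TUBB1, KDM2B, HDAC7, NME1, PRMT5, POLR2J, CEBPB, HMOX2 and RUNDC3A, and without a stated strand such reads cannot be assigned.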

Results

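RNA was sequenced from human erythroid cells grown from CD34-positive blood progenitors in a semi-synchronous culture, in 2 replicate samples collected on day 7 and 2 on day 10. The labels give CD34 cells as the source, whereas the design text speaks of CD36 cultures, and the labels do not resolve this. The series compares these days within a study of maturing erythroblasts, chromatin modifications and RNA polymerase II occupancy. Counts taken once per gene summed to 33694173 and 27652753 in the day 7 libraries and to 28522325 and 28726378 in the day 10 libraries. At least 10 counts were found for 13722 ± 156 genes on day 7 and 12063 ± 117 on day 10 (SD, n = 2 each). The labels do not say whether the replicates came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. All values below are relative to the other transcripts of the same library.

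Globin transcripts made up 5.62% ± 0.0175 of gene counts on day 7 and 35.3% ± 0.912 on day 10 (SD, n = 2 each), 6.29 times as much. Both day 10 libraries lay above both day 7 libraries, and an exact two-sided permutation test gave p = 0.33, the smallest p that 2 against 2 samples allow. With transcript counts summed per gene, the share rose by 17.2 percentage points in place of 29.7. HBB, the adult beta globin, rose from 12348 ± 109 to 192933 ± 9289 CPM (TMM-scaled, mean ± SD, n = 2 per day here and below), a log2 fold change of 3.97 ± 0.04 (SE here and below). The alpha globins HBA2 and HBA1 changed by 4.38 ± 0.04 and 4.31 ± 0.04, and the fetal gamma globin HBG2 by 1.67 ± 0.08. Reads of HBA1 and HBA2, and of HBG2 and HBG1, cannot be told apart with certainty because the copies are nearly identical. On day 10, HBA1 stood at 153052 CPM and HBA2 at 159726 CPM. Reads with 2 equal placements appear to be counted at both. The globin shares of both days, and their rise, may therefore count such reads more than once and be too high. HBM changed by 3.54 ± 0.06, whereas the embryonic zeta globin HBZ fell from 44.3 ± 0.352 to 12.02 ± 2.51 CPM. Of the globin list, 9 of 10 tested members rose and 1 fell, or 7 and 2 with library totals (median log2 fold change 2.54; adjusted p = 0.0018 and 0.43 with an estimated correlation). The adjusted p of a list, here and below, is that of limma's camera, first with its preset correlation. With an estimated correlation, camera also relies on the few residual degrees of freedom of 4 libraries. A list then had little chance of passing, so that second value decides little.

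Between day 7 and day 10, 5385 of 13627 tested genes rose and 6010 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among called genes with at least 20 CPM on the higher day and both day 10 values on one side of both day 7 values, the largest rise was in TMCC2 (NM_001297613 in the files), from 10.1 ± 1.06 to 2459 ± 170.0 CPM, a log2 fold change of 7.92 ± 0.08. IFIT1B rose from 1.08 ± 0.381 to 225 ± 8.34 CPM, and the kinase-like stress gene TRIB3 rose from 4.62 ± 0.1899 to 444 ± 4.47 CPM. ABCC13, TCP11L2 and RUNDC3A changed by 7.51 ± 0.17, 6.76 ± 0.06 and 6.54 ± 0.08. The long non-coding RNA MIAT changed by 6.51 ± 0.07 and the phosphatase DUSP5 by 6.50 ± 0.13. Large falls were in MLC1 (NM_015166), from 177 ± 2.51 to 4.49 ± 1.62 CPM or -5.30 ± 0.12 on the log2 scale, and in SEMA4C, with -5.23 ± 0.14. The calcium-binding protein gene S100A4 fell from 349.9 ± 0.0329 to 14.3 ± 0.703 CPM. The plexin gene PLXND1 changed by -4.72 ± 0.08 and the non-coding RNA UCA1 by -4.51 ± 0.09. MIF, which has an overlapping antisense gene, changed by -4.60 ± 0.11. PPM1H changed by -4.73 ± 0.15, and by -5.46 without day 10 replicate 1.

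A test against a fold of 2 called 2270 rises and 2939 falls. In 91.3% of tested genes both day 10 values lay above, or both below, both day 7 values, where chance gives 33.3%. The split of calls rested on the scaling: rises were 47.3% of calls with TMM and 13.7% with library totals as the only scaling, which called 1709 rises and 10725 falls. The median log2 fold change of all genes was -0.10 with TMM and -1.31 with library totals. Upper-quartile factors, tried after seeing the data, gave a median of -0.41, with 36.6% of calls being rises. Over all tested genes in 10 classes of transcript length, the median log2 fold change was -0.17 in the shortest and 0.20 in the longest class. It did not rise steadily, being lowest in the second shortest class (-0.32). The rank correlation of the change with length was 0.071 across genes, which are not independent replicates. With this trend removed, tried after seeing the data, 22 lists were higher and 6 lower. Where library totals turn a value the other way, that value stands beside it in parentheses.

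**Figure D1:**
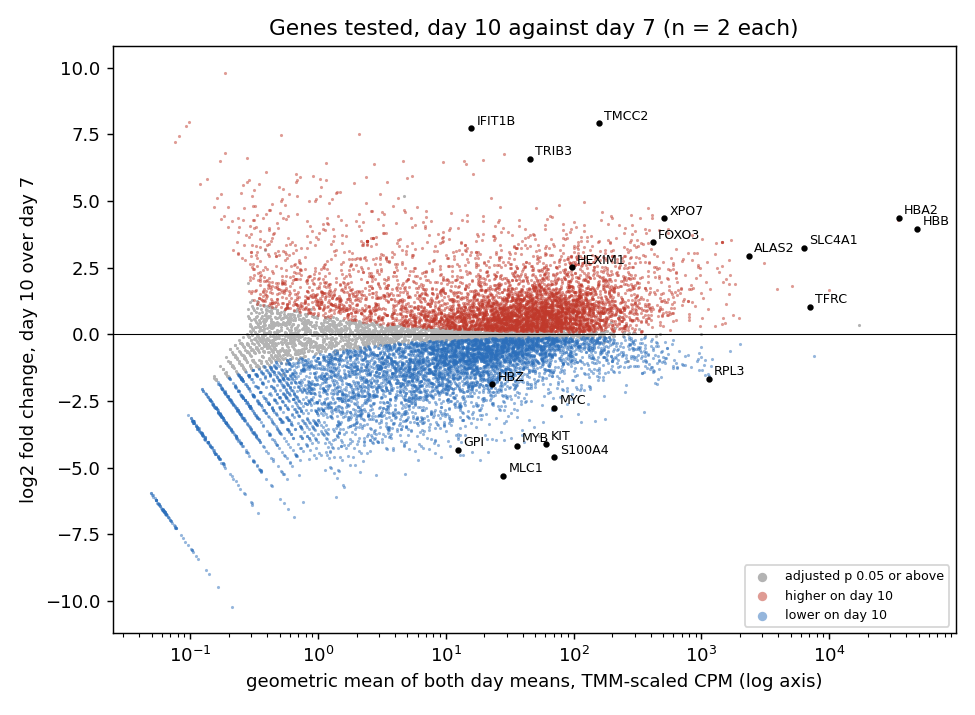
Log2 fold change of each tested gene (day 10 over day 7, vertical axis) against the geometric mean of its day means in TMM-scaled CPM (log axis), n = 2 libraries per day. Red points are the 5385 genes higher and blue points the 6010 genes lower on day 10 at an adjusted p under 0.05, with grey for the rest; with library totals only, these counts are 1709 and 10725.

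Genes known for high abundance in late erythroblasts rose together: 38 of 38 tested members rose and 0 fell, or 37 and 0 with library totals (median log2 fold change 3.22; adjusted p = 1.7e-13 and 0.38 with an estimated correlation). Besides TMCC2 and IFIT1B, the focal adhesion gene TNS1 rose from 74.7 ± 2.36 to 1972 ± 18.3 CPM. Among genes of the red cell membrane and its skeleton, 36 of 37 tested members rose and 1 fell, or 27 and 9 with library totals (median log2 fold change 2.01; adjusted p = 2.1e-10 and 0.31 with an estimated correlation). The urea transporter SLC14A1 rose from 3.8 ± 0.0347 to 132 ± 5.2 CPM, and BCAM, which carries the Lutheran antigens, changed by 4.25 ± 0.08. Band 3, encoded by SLC4A1, rose from 2037 ± 50.05 to 19486 ± 153 CPM. The adducin gene ADD2 changed by -0.45 ± 0.03. Of heme synthesis genes, 13 of 16 tested members rose and 2 fell, or 10 and 6 with library totals (median log2 fold change 1.54; adjusted p = 0.00079 and 0.43 with an estimated correlation). The mitochondrial iron importer SLC25A37 changed by 3.53 ± 0.04, ALAS2, the first enzyme of erythroid heme synthesis, by 2.94 ± 0.03, and the heme exporter FLVCR1 by -2.01 ± 0.15. Of genes for iron uptake and handling, 14 of 18 tested members rose and 4 fell, or 6 and 11 with library totals (median log2 fold change 0.99, -0.23 with library totals; adjusted p = 0.0069 and 0.35 with an estimated correlation). NCOA4, the receptor for ferritin breakdown, rose from 397 ± 4.51 to 4277 ± 0.657 CPM; ISCU changed by 3.08 ± 0.06. The transferrin receptor gene TFRC changed by 1.04 ± 0.04 (-0.18 with library totals).

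Among erythroid transcription factors, 22 of 25 tested members rose and 3 fell, or 13 and 11 with library totals (median log2 fold change 1.37; adjusted p = 5.2e-05 and 0.41 with an estimated correlation). SOX6 rose from 19.5 ± 0.648 to 346 ± 24.1 CPM and FOXO3 from 125 ± 9.83 to 1373 ± 54.1 CPM, whereas STAT5A changed by -3.77 ± 0.07. KLF1 changed by 1.55 ± 0.04, TAL1 by 2.32 ± 0.03 and GATA1 by 0.98 ± 0.04 (-0.24 with library totals). GATA2 stood at 13.98 ± 0.141 CPM on day 7 and 17.4 ± 2.101 on day 10, 0.31 ± 0.09 (-0.90 with library totals); its call was lost without day 7 replicate 1, day 7 replicate 2 or day 10 replicate 2, where the change was 0.29, 0.31 and 0.18. Of stem and progenitor genes, 4 of 19 tested members rose and 10 fell, a list that did not pass the test (median log2 fold change -0.86; adjusted p = 0.081 and 0.38 with an estimated correlation, with 2 rising and 16 falling with library totals). MYB fell from 152 ± 1.21 to 8.41 ± 1.29 CPM, the stem cell factor receptor KIT from 251 ± 2.54 to 14.5 ± 1.94 CPM and MYC from 183 ± 1.21 to 27.2 ± 0.946 CPM. Of cytokine and glucocorticoid signalling genes, 17 of 24 tested members rose and 6 fell, or 11 and 13 with library totals (median log2 fold change 0.96, -0.26 with library totals; adjusted p = 0.0070 and 0.34 with an estimated correlation). The glucocorticoid-induced gene TSC22D3 changed by 3.76 ± 0.07, the erythropoietin receptor EPOR by 1.73 ± 0.04 and the kinase LYN by -3.94 ± 0.12. Regulators of the fetal globin programme did not pass as a list, with 8 rising and 5 falling of 14 (adjusted p = 0.28 and 0.58 with an estimated correlation, with 6 rising and 8 falling with library totals).

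**Figure D2:**
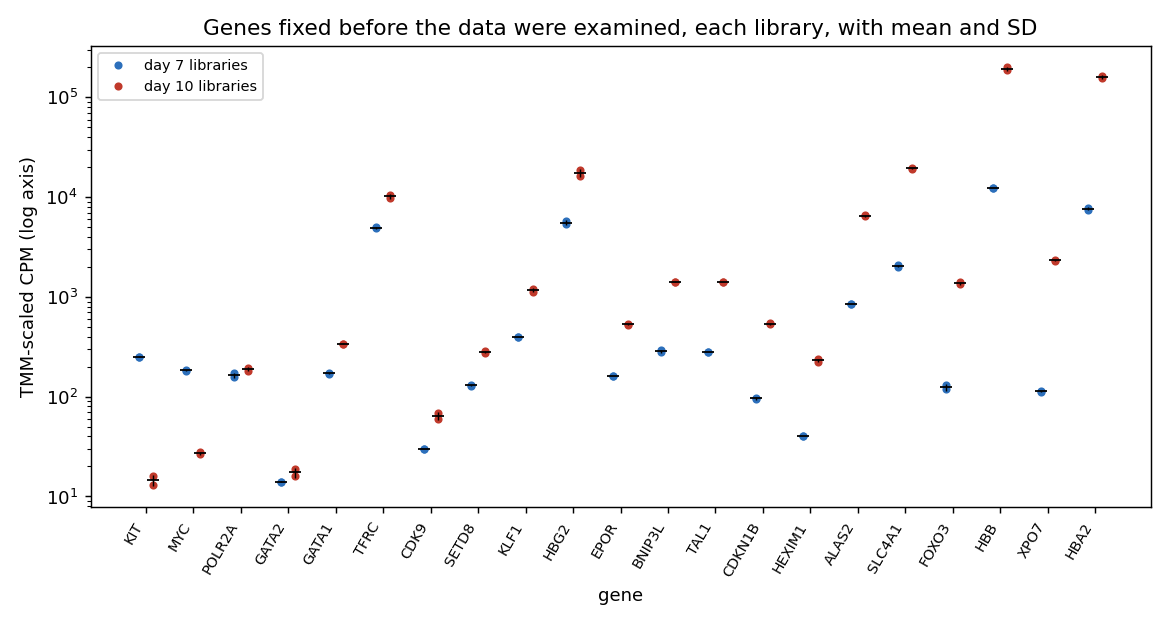
TMM-scaled CPM (log axis) of the genes fixed in advance that are reported here, in each day 7 library (blue) and day 10 library (red), ordered by log2 fold change; black marks are the day means with SD, n = 2. KIT fell from 251 ± 2.54 to 14.5 ± 1.94 CPM, and HBA2 rose from 7674 ± 290.2 to 159726 ± 6829 CPM. With library totals as the only scaling, POLR2A, GATA1, GATA2, TFRC, CDK9 and SETD8 lie lower on day 10.

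Genes of RNA polymerase II pausing and elongation did not pass as a list, although 24 of 42 tested members rose and 14 fell (median log2 fold change 0.35, -0.87 with library totals; adjusted p = 0.082 and 0.38 with an estimated correlation, with 5 rising and 34 falling with library totals). The list passed without day 10 replicate 1 (adjusted p = 0.048). HEXIM1, which holds the elongation kinase P-TEFb inactive, rose from 40.4 ± 0.2096 to 231 ± 8.97 CPM, and CDK9, the kinase of P-TEFb, changed by 1.09 ± 0.06 (-0.13 with library totals). AFF1 and TCEA1 changed by 2.49 ± 0.05 and 2.10 ± 0.04, and the PAF complex gene LEO1 by -1.20 ± 0.07. NELFE, of the pausing complex NELF, is among the genes of the histocompatibility block with counts near 0 and was not measurable here. Of the subunits of RNA polymerase II itself, 4 of 12 tested members rose and 7 fell (median log2 fold change -0.33; adjusted p = 0.41 and 0.58 with an estimated correlation, with 0 rising and 12 falling with library totals). POLR2J, whose exons overlap those of LRWD1, changed by 0.54 ± 0.06 (-0.68 with library totals) and POLR2G by -0.95 ± 0.07. The largest subunit, POLR2A, changed by 0.20 ± 0.05 (-1.02 with library totals), and its call was lost without day 7 replicate 1 (log2 fold change 0.13). Mediator genes passed with a small shift: 20 of 32 tested members rose and 5 fell, or 2 and 28 with library totals (median log2 fold change 0.24, -0.98 with library totals; adjusted p = 0.015 and 0.34 with an estimated correlation). This median was -0.07 with upper-quartile factors. MED17 changed by 2.25 ± 0.05 and MED6 by -0.40 ± 0.07. Of general transcription factors, 12 of 30 rose and 10 fell (adjusted p = 0.66 and 0.72 with an estimated correlation, with 2 rising and 26 falling with library totals).

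Of histone acetyltransferase genes, 21 of 26 tested members rose and 5 fell, or 6 and 16 with library totals (median log2 fold change 0.77, -0.45 with library totals; adjusted p = 0.0014 and 0.34 with an estimated correlation). EP300, a long transcript that differed 1.24 times between the day 10 libraries, rose from 83.7 ± 3.69 to 914 ± 132 CPM and KAT2B from 111 ± 0.587 to 619.7 ± 4.95 CPM, whereas KAT2A fell from 30.9 ± 1.76 to 3.03 ± 0.477 CPM. Of histone demethylase genes, 16 of 20 tested members rose and 4 fell, or 7 and 9 with library totals (median log2 fold change 1.13, -0.09 with library totals; adjusted p = 0.0038 and 0.43 with an estimated correlation). KDM7A changed by 3.76 ± 0.07 and KDM2B, whose exons overlap those of RNF34, by -1.85 ± 0.07. Of histone methyltransferase genes, 22 of 35 tested members rose and 11 fell, or 5 and 24 with library totals (median log2 fold change 0.79, -0.43 with library totals; adjusted p = 0.047 and 0.38 with an estimated correlation); adjusted over the list alone, 23 rose. That call was also lost with DESeq2 size factors (adjusted p = 0.052), library totals (adjusted p = 0.22), a stricter count filter (adjusted p = 0.059), the length trend removed (adjusted p = 0.095) and without day 7 replicate 1 (adjusted p = 0.061) or day 7 replicate 2 (adjusted p = 0.057). EZH1 changed by 2.40 ± 0.05, the H4K20 methyltransferase SETD8 by 1.12 ± 0.04 (-0.10 with library totals) and the arginine methyltransferase PRMT5, which has an overlapping antisense gene, by -2.01 ± 0.06. Histone deacetylase genes did not pass as a list, with 15 rising and 15 falling of 33 (adjusted p = 0.75 and 0.75 with an estimated correlation, with 2 rising and 28 falling with library totals). HDAC5 changed by 2.84 ± 0.06 and HDAC7, whose exons overlap those of SLC48A1, by -2.85 ± 0.07. Of replication-dependent histone genes, 18 of 22 tested members rose and 0 fell, or 6 and 3 with library totals (median log2 fold change 1.17, -0.04 with library totals; adjusted p = 0.00048 and 0.42 with an estimated correlation). HIST1H1C rose from 4.21 ± 0.054 to 90.5 ± 3.86 CPM and HIST2H2BE from 1.25 ± 0.178 to 9.28 ± 0.533 CPM. Replication-independent histones and chaperones did not pass as a list (19 of 30 tested members rose and 10 fell; adjusted p = 0.059 and 0.71 with an estimated correlation, with 8 rising and 18 falling with library totals; adjusted p = 0.031 without day 10 replicate 1), with the linker histone H1F0 changing by 3.90 ± 0.04 and the chaperone NASP by -1.55 ± 0.04.

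Ribosomal protein genes fell together: 1 of 76 tested members rose and 72 fell, or 0 and 75 with library totals (median log2 fold change -0.98; adjusted p = 2.4e-11 and 0.48 with an estimated correlation). RPL23 fell from 529.6 ± 2.23 to 119.8 ± 3.26 CPM and RPL10A from 497 ± 3.64 to 133 ± 3.84 CPM. Many of these genes share sequence with processed pseudogenes, and RPS18 had 2 counts over the 4 libraries. The list of ribosome biogenesis and MYC-associated nucleolar genes fell: 3 of 44 tested members rose and 40 fell, or 0 and 44 with library totals (median log2 fold change -2.02, adjusted p = 1.5e-08 and 0.31 with an estimated correlation). RRP9 fell from 22.4 ± 0.0967 to 1.595 ± 0.425 CPM, NME1, which shares exons with a read-through gene, changed by -3.47 ± 0.08, and the polyamine enzyme gene ODC1 by 0.94 ± 0.04 (-0.28 with library totals). Translation factors did not pass as a list (12 of 42 tested members rose and 30 fell; adjusted p = 0.052 and 0.58 with an estimated correlation, with 2 rising and 40 falling with library totals). DNA replication and G1/S genes fell: 11 of 47 tested members rose and 33 fell, or 2 and 43 with library totals (median log2 fold change -0.45; adjusted p = 0.018 and 0.34 with an estimated correlation). The uracil glycosylase UNG changed by -3.53 ± 0.09 and E2F2 by 3.16 ± 0.04. Genes of G2/M and mitosis rose relative to other genes: 42 of 44 tested members rose and 2 fell, or 6 and 27 with library totals (median log2 fold change 0.98, -0.24 with library totals; adjusted p = 2.9e-08 and 0.31 with an estimated correlation). FZR1, a mitotic exit activator, changed by 2.84 ± 0.05, NUSAP1 by 1.75 ± 0.04 and MAD2L1 by -0.28 ± 0.05. Of genes for cell cycle exit, 21 of 30 tested members rose and 5 fell, or 12 and 16 with library totals (median log2 fold change 0.85, -0.37 with library totals; adjusted p = 0.0018 and 0.34 with an estimated correlation). The CDK inhibitor CDKN2D rose from 5.89 ± 0.201 to 109.9 ± 3.77 CPM and CDKN1B from 96.3 ± 2.55 to 536 ± 8.75 CPM, and CCND2 changed by -2.43 ± 0.12.

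Of autophagy and mitophagy genes, 36 of 46 tested members rose and 6 fell, or 26 and 18 with library totals (median log2 fold change 1.603; adjusted p = 5.7e-07 and 0.35 with an estimated correlation). GABARAPL1 rose from 9.89 ± 0.651 to 264 ± 16.4 CPM and the starting kinase ULK1 from 25.8 ± 0.723 to 416 ± 22.2 CPM. BNIP3L, the mitophagy receptor of reticulocytes, changed by 2.31 ± 0.04. Its relative BNIP3 changed by -2.22 ± 0.25, a call lost without day 10 replicate 1 or day 10 replicate 2, where the change was -2.27 and -2.17. Of ubiquitin enzymes described in erythroblasts, 29 of 31 tested members rose and 1 fell, or 23 and 7 with library totals (median log2 fold change 2.19; adjusted p = 2.4e-09 and 0.34 with an estimated correlation). UBE2H rose from 44.1 ± 1.05 to 915 ± 38.6 CPM, TRIM58 changed by 3.81 ± 0.04 and CAND1 by -0.21 ± 0.05. Proteasome genes did not pass as a list (19 of 34 tested members rose and 10 fell; adjusted p = 0.24 and 0.72 with an estimated correlation, with 1 rising and 33 falling with library totals). The list passed as higher with the length trend removed (adjusted p = 0.024). Of genes tied to nuclear condensation and enucleation, 28 of 38 tested members rose and 9 fell, or 10 and 25 with library totals (median log2 fold change 0.76, -0.45 with library totals; adjusted p = 0.00096 and 0.34 with an estimated correlation). The exportin XPO7 rose from 113 ± 1.09 to 2323 ± 27.1 CPM, and lamin B1 (LMNB1) changed by -1.04 ± 0.04.

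Of the integrated stress and unfolded protein response list, 25 of 29 tested members rose and 4 fell, or 17 and 10 with library totals (median log2 fold change 1.95; adjusted p = 1.8e-05 and 0.35 with an estimated correlation). CEBPB, which has an overlapping antisense gene, changed by 3.36 ± 0.05 and the chaperone PDIA4 by -2.53 ± 0.08. Of antioxidant genes, 21 of 26 tested members rose and 4 fell, or 11 and 15 with library totals (median log2 fold change 0.77, -0.45 with library totals; adjusted p = 0.00071 and 0.43 with an estimated correlation). Heme oxygenase 1 (HMOX1) rose from 5.93 ± 1.02 to 116 ± 6.69 CPM, HMOX2, whose exons overlap those of NMRAL1, changed by -1.49 ± 0.16 and PRDX3 by -1.08 ± 0.05. Of p53 target genes, 18 of 23 tested members rose and 4 fell, or 8 and 15 with library totals (median log2 fold change 0.48, -0.74 with library totals; adjusted p = 0.0024 and 0.34 with an estimated correlation). GDF15 changed by 4.45 ± 0.04 and ZMAT3 by -1.93 ± 0.12. Of apoptosis regulators, 16 of 25 tested members rose and 8 fell, or 7 and 16 with library totals (median log2 fold change 0.74, -0.48 with library totals; adjusted p = 0.039 and 0.38 with an estimated correlation), a call also lost without day 10 replicate 2 (adjusted p = 0.057). The survival gene BCL2L1 rose from 86.7 ± 1.36 to 1943 ± 86.2 CPM, and BID changed by -3.04 ± 0.11. Chaperones and heat shock genes did not pass (9 of 25 tested members rose and 13 fell; adjusted p = 0.39 and 0.72 with an estimated correlation, with 1 rising and 22 falling with library totals).

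Of nuclear-encoded oxidative phosphorylation genes, 9 of 52 tested members rose and 33 fell, or 0 and 52 with library totals (median log2 fold change -0.37; adjusted p = 0.0040 and 0.48 with an estimated correlation). ATP5G1 changed by -2.66 ± 0.08 and COX6B1 by 0.45 ± 0.06 (-0.77 with library totals). Genes of glycolysis and glucose transport did not pass as a list (9 of 28 tested members rose and 18 fell; adjusted p = 0.15 and 0.71 with an estimated correlation, with 5 rising and 22 falling with library totals). BPGM, which makes the red cell's bisphosphoglycerate, rose from 34.5 ± 0.184 to 819.9 ± 18.1 CPM, and the glucose transporter SLC2A1 rose from 292 ± 1.41 to 3468 ± 147 CPM. The glycolytic enzyme gene GPI fell from 55.4 ± 3.89 to 2.77 ± 0.3304 CPM, and LDHB from 356 ± 5.71 to 36.1 ± 1.66 CPM. Of spliceosome genes, 8 of 47 tested members rose and 32 fell, or 0 and 47 with library totals (median log2 fold change -0.30; adjusted p = 0.0070 and 0.34 with an estimated correlation). SNRPE changed by -1.75 ± 0.06 and SF3B1 by 1.00 ± 0.04 (-0.21 with library totals). Lists for the nuclear pore (adjusted p = 0.36 and 0.72 with an estimated correlation), mRNA decay (adjusted p = 0.40 and 0.57 with an estimated correlation), cholesterol synthesis (adjusted p = 0.71 and 0.72 with an estimated correlation), hypoxia (adjusted p = 0.97 and 0.98 with an estimated correlation) and widely used reference genes (adjusted p = 0.97 and 0.98 with an estimated correlation) did not pass. Of the reference genes, 14 of 27 tested members rose and 12 fell, against 2 and 25 with library totals. For cholesterol synthesis, histone deacetylases, reference genes and the mast cell group, the median and the mean log2 fold change differed in sign.

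Of the lists for other blood cell types, that of megakaryocytes and platelets passed as lower, those of mast cells, granulocytes and monocytes did not pass, and that of lymphocytes had too few measured members for the test. Of megakaryocyte and platelet markers, 2 of 20 tested members rose and 18 fell, or 0 and 20 with library totals (median log2 fold change -3.46; adjusted p = 0.00058 and 0.48 with an estimated correlation). PLEK fell from 53.9 ± 0.693 to 3.25 ± 0.0546 CPM, and MMRN1 changed by -4.08 ± 0.17, or -4.78 without day 10 replicate 1. The 2 that rose were TUBB1, at 0.94 ± 0.04 (-0.28 with library totals), whose exons overlap those of ATP5E, and LTBP1, at 0.33 ± 0.06 (-0.88 with library totals). Of mast cell, basophil and eosinophil markers, 7 of 13 tested members rose and 4 fell (adjusted p = 0.40 and 0.67 with an estimated correlation, with 0 rising and 11 falling with library totals). Here LMO4 changed by 1.02 ± 0.06 (-0.20 with library totals), CLC by 0.85 ± 0.06 (-0.37 with library totals) and ENPP3 by -3.05 ± 0.19. Of granulocyte markers, 3 of 11 tested members rose and 2 fell (adjusted p = 0.39 and 0.58 with an estimated correlation, with 0 rising and 8 falling with library totals). SRGN changed by 0.65 ± 0.05 (-0.57 with library totals) and lysozyme (LYZ) by -0.31 ± 0.12, a call lost with DESeq2 size factors (-0.25), with DESeq2's Wald test (-0.24) and without day 7 replicate 1 (-0.20), day 10 replicate 1 (-0.32) or day 10 replicate 2 (-0.29). Of monocyte and macrophage markers, 2 of 6 tested members rose and 4 fell (adjusted p = 0.66 and 0.72 with an estimated correlation, with 0 rising and 4 falling with library totals). CD68 fell from 8.17 ± 0.472 to 3.33 ± 0.395 CPM. Lymphocyte markers had 4 testable members, of which 3 fell, too few for the list test. Immediate early genes, which can respond to handling of cells, rose: 14 of 16 tested members rose and 2 fell, or 11 and 4 with library totals (median log2 fold change 1.96; adjusted p = 0.00063 and 0.34 with an estimated correlation). MAFF changed by 3.43 ± 0.14 and EGR1 by 3.24 ± 0.07. The ribosomal RNA precursor held 2.33% ± 0.213 of gene counts on day 7 and 1.27% ± 0.3398 on day 10 (SD, n = 2).

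In all, 22 lists rose and 6 fell of 47 tested by camera with its preset correlation. With a correlation estimated from these 4 libraries, camera called 0 lists, 3 had an unadjusted p under 0.05, and fry called 32 higher and 14 lower. These 0 calls decide little, because the few residual degrees of freedom of 4 libraries left a list little chance of passing. With library totals the calls for G2/M genes (adjusted p = 0.068), histone acetyltransferases (adjusted p = 0.087), histone methyltransferases (adjusted p = 0.22) and Mediator (adjusted p = 0.75) were lost. With library totals the lists of the proteasome (adjusted p = 0.032, although its median lay 0.21 above that of all genes), translation factors (adjusted p = 0.014) and nuclear pore (adjusted p = 0.042) passed as lower and that of fetal globin regulators (adjusted p = 0.032) as higher. Adjusted over the list alone, the counts of members that rose and fell were those over all genes except for histone methyltransferases.

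**Figure D3:**
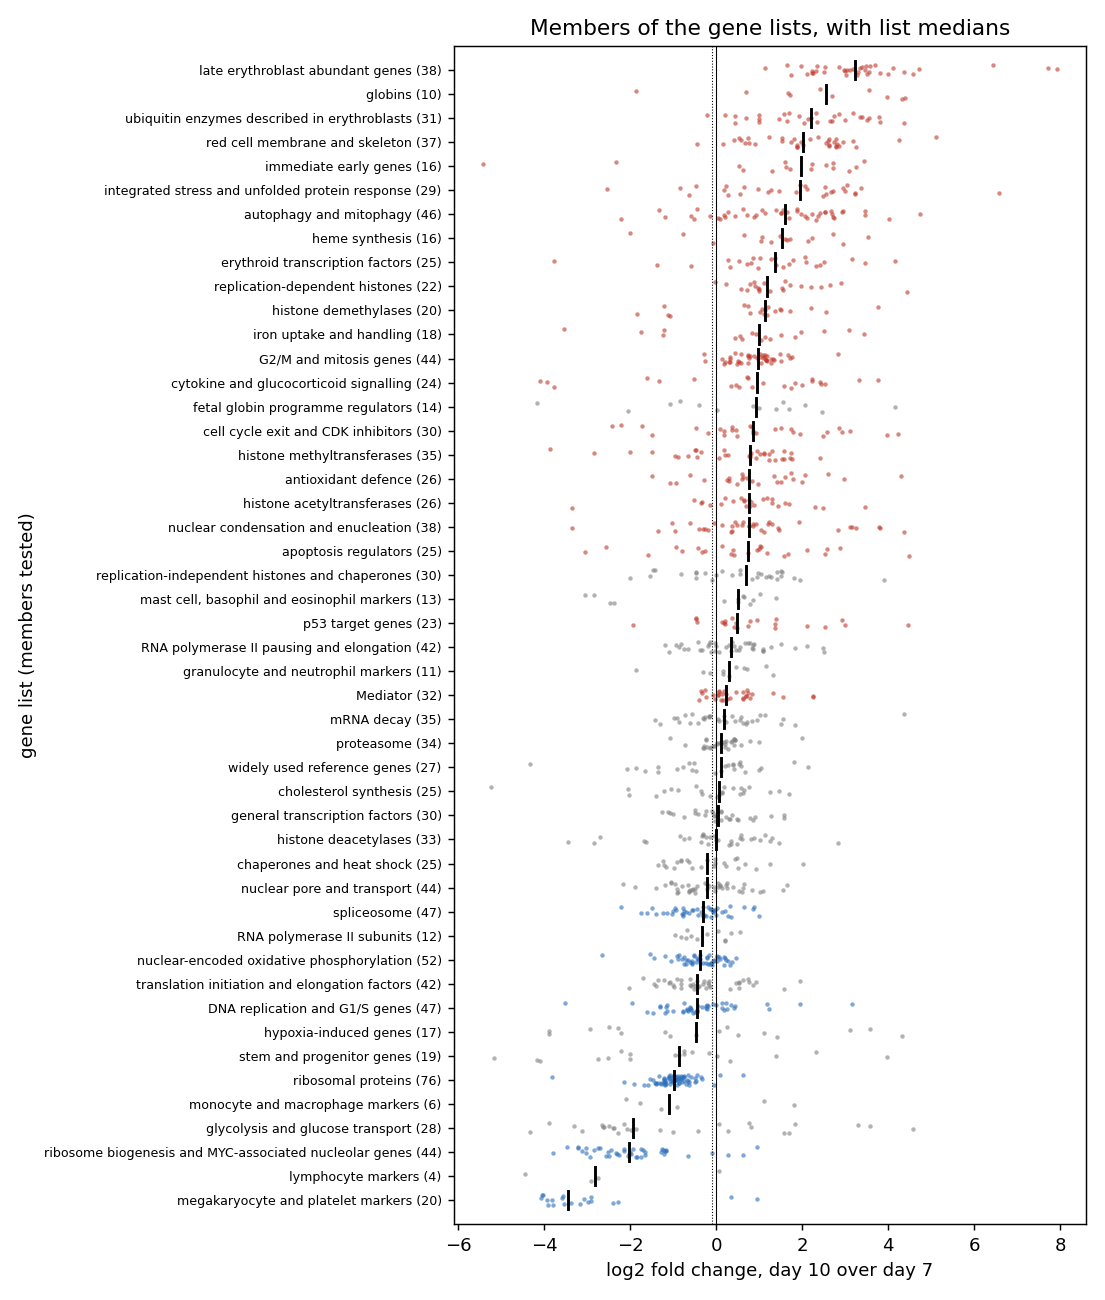
Log2 fold change (day 10 over day 7) of each tested member of the gene lists, with list medians as black bars and the number of members tested in parentheses; n = 2 libraries per day. Red lists rose and blue lists fell against all other genes by camera at its preset correlation, grey lists did not pass, and the dotted line is the median of all genes (-0.10). The late erythroblast list lies highest (median 3.22) and the megakaryocyte list lowest (-3.46); with library totals the medians of 13 of the red lists are below 0.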

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

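Upper-quartile factors, leaving out the histocompatibility block, an estimated fold of 2 and removing the length trend were tried only after the data were seen. Counts of genes higher and lower on day 10 stayed within 1.5 times 5385 and 6010 with DESeq2 size factors, TMM without globin genes, other count filters, DESeq2's Wald test (5154 and 5045), summed transcripts, upper-quartile factors (4223 and 7317) and leaving out the histocompatibility block. Leaving out each library gave 4948 to 5385 genes higher and 5362 to 5808 lower. They moved with library totals (1709 and 10725), where 2717 calls turned round and the median of all genes shifted by -1.22, and with upper-quartile factors the median shifted by -0.31. The stricter question of a fold of 2 left 2270 and 2939, and requiring an estimated fold of 2 left 2722 and 3636. Testing transcripts gave 11944 and 13267 because more features are tested. With the replicate number as a block, 5283 genes were higher and 5862 lower. Same-numbered libraries did not deviate together (correlation -0.034 across 9272 genes). With only 2 pairs this cannot exclude that same-numbered libraries share an origin, which the labels do not give.

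Lists called higher and lower (22 and 6) became 0 and 0 with camera's correlation estimated. There the lowest adjusted p was 0.306 and 3 lists had an unadjusted p under 0.05. For these 3 (red cell membrane, ribosome biogenesis and MYC-associated genes, G2/M) the estimated correlations were -0.012, -0.023 and -0.0016, below the preset 0.01. Their unadjusted camera p still went from 1.3e-11, 1.6e-09 and 3.8e-09 to 0.016, 0.019 and 0.0195. A higher correlation among members is thus not the whole cause for them. In this setting camera also takes its p from the few residual degrees of freedom of 4 libraries, in place of the number of genes. A list therefore had little chance of passing, and the 0 calls decide little. Fry, which compares no list with other genes, called 32 and 14. Leaving out each library gave 21 to 24 and 6 lists, removing the length trend 22 and 6, and the replicate block 21 and 6, where apoptosis regulators had an adjusted p of 0.059. Of single list results, 453 kept direction and call, 38 lost the call, 22 gained one and 4 turned round. With library totals, camera gave the proteasome (adjusted p = 0.032) and Mediator (adjusted p = 0.75) as lower, although their medians lay 0.21 and 0.33 above that of all genes. Fry gave hypoxia-induced genes as higher and reference genes as lower, against the direction of camera, with medians of -0.37 and 0.21 relative to all genes; the cause was not tested. The rise in globin share was 29.7 percentage points, 29.1 to 30.4 without each library and 17.2 with transcripts summed, which counts reads of multi-transcript genes several times and so enlarges the total. Reads of near-identical globin copies, if counted at both, would make the 29.7 points too large.

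Of the named genes' log2 fold changes, 1294 values under the alternatives kept their direction and call, 11 kept only their direction (GATA2, BNIP3, POLR2A and LYZ) and 15 turned round, each with library totals: TFRC -0.18, GATA1 -0.24, GATA2 -0.90, POLR2J -0.68, POLR2A -1.02, CDK9 -0.13, SETD8 -0.10, ODC1 -0.28, COX6B1 -0.77, SF3B1 -0.21, TUBB1 -0.28, LTBP1 -0.88, LMO4 -0.20, CLC -0.37, SRGN -0.57. By construction, that scaling lowers the log2 fold change of every gene alike, by about the shift of the median given above, and so turns smaller rises. Depth limits genes with few counts on both days, and genes under the count filter were not tested.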

Other observations

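The gene families and genes of the first 2 paragraphs and the 3 patterns below were chosen after their values were seen, as were all tests of the patterns except the random lists matched on length and mean count and the check of GC content. Adjusted p of gene families cover the 12 symbol families run. The camera p with an estimated correlation are not adjusted over these families, and the lowest of them, 0.034, is not a call. Genes of the mitochondrial ribosome fell, as did those of the cytosolic one. Of MRPL genes, 4 of 50 tested rose and 40 fell (median log2 fold change -0.76, camera adjusted p = 2.0e-05, unadjusted p = 0.090 with an estimated correlation), with MRPL12 falling from 54.5 ± 0.472 to 12.8 ± 1.68 CPM (SD, n = 2 per day here and below). Of MRPS genes, 0 of 29 tested rose and 26 fell (median log2 fold change -0.84, camera adjusted p = 1.7e-05, unadjusted p = 0.034 with an estimated correlation), with MRPS12 falling from 20.3 ± 0.676 to 6.48 ± 0.523 CPM. Of genes with ZNF symbols, most of which encode zinc finger proteins, 90 of 466 tested rose and 275 fell (median log2 fold change -0.54, camera adjusted p = 0.0012, unadjusted p = 0.057 with an estimated correlation). With library totals, 15 ZNF genes rose and 436 fell, against 0 and 49 for MRPL and 0 and 29 for MRPS. Small nucleolar RNA genes (115 tested) did not pass as a family, with a camera adjusted p of 0.058. Neither did SLC and LINC symbols (camera adjusted p = 0.63 and 0.25). HIST, RAB, USP, UBE2 and MIR symbols passed as higher (camera adjusted p = 1.7e-05, 0.011, 0.026, 0.013 and 0.032). With library totals, all of these but HIST had more falls than rises. MIR1281 and MIR6073 share exon bases with EP300 and SOX6 on the same strand, so counts of MIR symbols may include reads of other genes. Of genes with KLF symbols, the Krüppel-like factors and an antisense gene, 11 of 14 tested rose and 2 fell (median log2 fold change 1.44, camera adjusted p = 0.0094, unadjusted p = 0.18 with an estimated correlation). KLF13 changed by 2.10 ± 0.04 and KLF9 by 2.02 ± 0.06 (log2 fold change ± SE), whereas KLF16 changed by -1.23 ± 0.06; with library totals, 7 rose and 2 fell.

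Of non-coding RNAs, NEAT1 rose from 600.1 ± 14.98 to 3560.0 ± 26.1 CPM and MALAT1 from 766 ± 42.7 to 3204 ± 325 CPM, and both stayed higher with library totals (1.35 and 0.85 on the log2 scale), whereas SNHG1 changed by -0.75 ± 0.05. Genes induced by interferon were not tested as a list; of single ones, RSAD2 rose from 21.3 ± 0.189 to 675 ± 5.13 CPM, IFIT2 changed by 2.34 ± 0.12, IFIT3 by 1.48 ± 0.05 and IRF7 by 2.41 ± 0.15. By contrast IFITM1 changed by -4.60 ± 0.27, IFITM3 by -3.67 ± 0.25 and IFI44 by -2.31 ± 0.21, while ISG15 stood at 2.701 ± 0.327 and 2.61 ± 0.559 CPM (adjusted p = 0.80 by edgeR).

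Most genes of the major histocompatibility block had few or no counts. Of 158 protein-coding genes between TRIM27 and DAXX, 5.7% reached a mean of 100 counts, against 50.8% of 18754 elsewhere, and RPS18 had 2 counts where the lowest of 76 other ribosomal protein genes had a mean of 4962, which argues against low depth. The lengths implied by FPKM were 6.07 times the longest annotated transcript in the block (median) and 0.989 times elsewhere, as they would be if several copies of each gene were listed. A candidate explanation is that reads with many equal placements on alternative copies of the block were dropped before counting. No biological explanation was tested, and NELFE and EHMT2 cannot be read in these tables.

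Ribosomal protein genes fell around a median log2 fold change of -0.98, which lay -0.879 from that of all genes, whereas globin counts displacing others would lower all other genes alike. Genes of similar length and day 7 level did not fall as much. Matched on both, 10000 random lists had a mean median of 0.11 ± 0.31 (SD), a difference of -1.09, with -0.85 the lowest. As many matched on length alone had -0.09 ± 0.17, a difference of -0.889, with -0.84 the lowest. These means argue against an equal loss of all short or abundant transcripts as the whole cause. List members were drawn independently, whereas ribosomal protein genes had an estimated correlation of 0.55. The SD and lowest value are therefore too narrow for such a set, and the closeness of the matches was not checked. The match planned first, on length and the mean count of both days (a difference of -1.78), decides nothing, since it favours genes that rose; reads shared with pseudogenes were not tested. A fall in ribosomal protein mRNA with day of culture stays open as a hypothesis, beside a change in the mixture of cells, which these libraries cannot separate.

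The longest transcripts differed between both day 10 libraries. Over 8523 genes, the median log2 ratio of replicate 1 to replicate 2 was 0.146 in the longest of 10 equal length classes and 0.206 above that of the shortest, while on day 7 the same difference was -0.05. DYNC1H1 and PRKDC, chosen after their values were seen, had ratios of 1.55 and 1.596 and EP300, named in the report, had 1.24. GC content is not the whole cause: across the 7500 genes with a value the rank correlation of the ratio with length was 0.397, and 0.344 given GC content, although GC kept a part of its own (-0.24 given length; genes are not independent replicates). Recovery that falls with transcript length, as in partly degraded RNA, may be the source, and no biological explanation was tested.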
